A study of Mus musculus with 6 samples.

How the data were processed

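Total RNA from whole hearts of male C57Bl6 mice was biotin-labelled and hybridised to Illumina bead arrays, 1 array per sample, per the labels' protocols. There were 6 arrays in 2 groups of 3: uninjured hearts, and hearts taken 72 h (3 days) after a 90 min occlusion of the left anterior descending coronary artery followed by reperfusion. The labels describe the control mice as having had no operation, whereas the column names of the deposited signal table call the control arrays sham. Which of these holds is not settled by the sources used here, and the group is called uninjured after the labels. If the controls had no operation, effects of the operation itself cannot be told apart from those of occlusion and reperfusion. The labels call the arrays replicates of each group without saying that each came from a separate mouse, so p-values measure the spread between these samples, which may be technical.

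The deposited table of probe intensities gives, per the file headers, the mean bead signal of 45281 probes and its detection p-value on each array. The bead signals were summarised with GenomeStudio 2010.3, per the submitters' processing notes. The deposited intensities carried no background subtraction and no normalization between arrays, as read from their values. The deposited detection p-values moved in steps of 1 in 936 on each array, as read from their values. The authors' processed values for the same arrays were also deposited as linear intensities, with column medians of 88.37 to 88.43. Their columns shared 1 minimum and 1 maximum, each ranked the probes exactly as 1 column of the signal table did (Spearman's rho of 1, across probes), and that column was of the same group in all 6 cases. This comparison placed them as quantile-normalized values on a linear scale without centring, and they were used only as an alternative. The signal columns give the group and a mouse or array number (109, 110 and 904 in the uninjured group, 106, 107 and 886 in the other) but no replicate number, so arrays are named by these numbers.

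The main values were computed from the signal table with limma 3.58.1 in R 4.3.3 (statmod 1.5.0 for the robust fit). The neqc function estimated the background from the detection p-values, applied the normexp correction, added an offset of 16, normalized by quantiles and took log2. Probes were kept where the detection p-value was under 0.05 on at least 3 of the 6 arrays, which left 18197 probes. Probe names came from the platform annotation, which can be old, with symbols looked up through Entrez identifiers in a RefSeq gene table of the mouse assembly GRCm38.p6, used for names only. Of all probes, 34885 had 1 symbol, 18 had several and 10378 had none. Probes with several symbols or none were normalized but entered no gene count. A gene took the value of its kept probe with the highest mean over all arrays, giving 10204 genes. Of these, 3819 had more than 1 kept probe, and 189 had probes called in opposite directions. Probes of near-identical family members, such as the globin and histone genes, can bind each other's transcripts.

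Groups were compared per gene with limma's lmFit and eBayes without a block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes refer to the scale of background-corrected intensity plus 16, which understates changes of dim genes. A gene counted as detected on an array where any of its probes was, kept or not. A gene whose probes were undetected on all 3 arrays of a group has only a bound there. For such a gene the text gives "at least N-fold", the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the gene's own value and the lowest value among detected probes. The number of arrays limits the precision of each value.

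Before the data were examined, 31 gene lists were fixed for cell types and pathways of the injured heart, together with the rule for naming genes. The rule took the 10 largest increases and the 10 largest decreases among changed genes whose groups did not overlap, leaving out accessions, clone names and predicted genes, then the 3 changed members of each list with the largest change, and Igf1, Igf1r, Mcpt4 and Cma1 because of the series title. This gave 98 genes. Lists with at least 3 measured members, 28 in number, were tested against all other genes with camera at a preset correlation of 0.01 and again with a correlation estimated for each list, with adjustment over the 28 lists. The NK cell, adipocyte and skeletal muscle lists were too small for the test. Lox is in the activated fibroblast and extracellular matrix lists, and no other gene is in more than 1. Differences between medians of lists were tested with two-sided permutation tests of 100000 resamples, or by exact permutation where a list had under 10 genes. These tests permute genes, which are treated as independent, so their p-values do not measure the spread between arrays.

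The steps were tested on simulated data for the comparison of 72 h against uninjured hearts, with 200 genes changed. Probe noise came from the real arrays, and 12841 genes passed the filter. The share called in the right direction was 37.0% at an absolute log2 change of 0.5, 78.3% at 1, 87.2% at 2 and 79.2% at 3. Of all calls, 5.71% were of unchanged genes. The simulated changes were few and even in direction, whereas 73.9% of genes were called in the real comparison. The simulated background had an assumed spread and the same mean on every array, and only 10204 genes passed the filter in the real data. These rates therefore need not hold for the real data.

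Alternatives varied the background correction, the scaling, the offset (50), the probe filter, the rule from probes to genes, the variance model, the arrays left out, and the correlation in the list test. The authors' processed values were a further alternative. A block for the slide was not run because the files give no slide. Ddx3y, planned for the check on sex, is not analysed here.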

Results

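The series measured gene expression in whole hearts of male C57Bl6 mice on Illumina bead arrays, with 3 arrays of uninjured hearts and 3 arrays of hearts taken 72 h after ischemia-reperfusion (IR), a 90 min occlusion of a coronary artery followed by return of flow. Its title concerns the degradation of the growth factor IGF-1 by mast cell chymase and delayed cell death after ischemia. The arrays measure transcripts, not IGF-1 or chymase protein. The comparison of the 2 groups asks which transcripts differ 72 h into reperfusion. Unless the controls had a sham operation, it cannot tell effects of the operation from those of IR. Between 15891 and 17843 probes were detected on the uninjured arrays and between 18013 and 19243 on the IR arrays. The 75th percentile of raw intensity was 109 to 111 in uninjured and 135 to 138 in IR hearts. Xist was detected on 0 of 6 arrays, while the Y-linked Eif2s3y, Kdm5d and Uty each had a probe detected on all 6.

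Relative to uninjured hearts, transcript levels 72 h after IR were higher for macrophage, neutrophil, matrix and cell division genes, and lower for genes of contraction, ion transport, fatty acid oxidation and the respiratory chain. These list calls rest on a preset correlation between genes. They were lost in the test with an estimated correlation, which has only the degrees of freedom of 6 arrays. The ion channel call was lost at an estimate of -0.00014, below the preset 0.01, so correlation does not account for that loss. The top increases were Gpnmb, a macrophage membrane glycoprotein, at 126-fold, and Timp1, an inhibitor of matrix metalloproteinases, at 123-fold. The top decrease was Ces1d, a carboxylesterase, at 78.2-fold lower. Igf1 rose 4.52-fold. Of 10204 genes tested with limma, 4022 rose and 3523 fell at an adjusted p under 0.05, together 73.9% of the genes, and 1533 rose and 1392 fell by at least 2-fold. The groups did not overlap in 76.7% of genes, against 10% by chance.

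The first principal component held 94.9% of the variance and parted the groups. Pearson correlations across genes, which are not independent replicates, were 0.990 to 0.991 among uninjured arrays, 0.995 to 0.997 among IR arrays and 0.824 to 0.840 between groups. Uninjured array 904 lay apart on the second component, at -16.7 against 7.65 and 9.53 for the others of its group, and 7505 genes changed without it. The split of calls depended on the scaling: 53.3% of changed genes rose after quantile normalization, 77.5% (6098 rose, 1775 fell) after scaling to a common median of all probes, and 42.7% (3324 rose, 4464 fell) after scaling to a common median of the kept probes, a choice made after the data were seen. The median log2 fold change of all genes was 0.05, 0.52 and -0.14 in these settings. Between 35.1% and 42.5% of probes were detected per array, so the median of all probes is the level of an undetected probe. Without background correction 1542 genes changed by at least 2-fold in place of 2925, and with the authors' processed values 1671, while scaling to the median of all probes gave 3695. The log2 fold changes of 50 of the 98 named genes were more than 1.5 times smaller without background correction, and 38 were moved as far by the authors' values, with the direction kept in each.

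**Figure D1:**
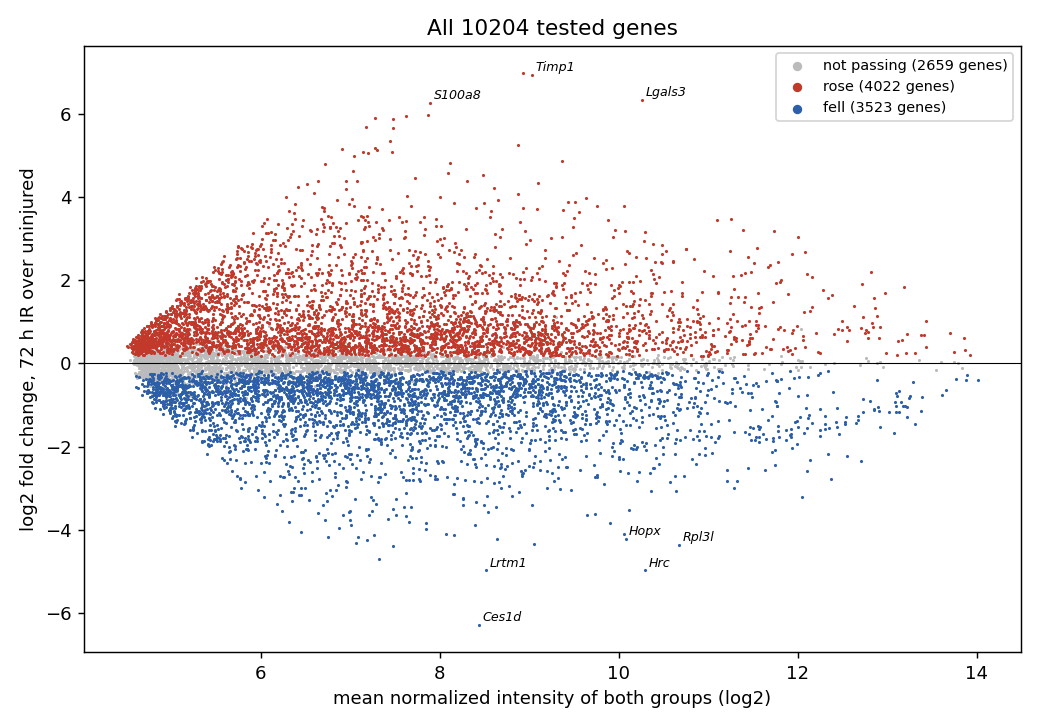
Log2 fold change (72 h after IR over uninjured, vertical axis) against mean normalized log2 intensity over both groups (horizontal axis) for the 10204 tested genes, with 4022 genes that rose in red, 3523 that fell in blue and 2659 not passing in grey. Genes named in the plot include Timp1 at 6.94 and Ces1d at -6.29; under scaling to the median of all probes the counts became 6098 and 1775.

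The remaining top increases included members of the macrophage, neutrophil and activated fibroblast lists. Lgals3, which encodes galectin-3, rose by 6.35 ± 0.08 on the log2 scale (SE, n = 3 per group), and S100a8, a subunit of calprotectin, by 6.27 ± 0.26, with S100a8 detected on 1 of 3 uninjured arrays. Lox, the collagen crosslinking enzyme, rose by 5.99 ± 0.21, Sprr1a by 5.95 ± 0.13 and Tnc, the matrix glycoprotein tenascin C, by 5.68 ± 0.10, each also detected on 1 of 3 uninjured arrays. Arg1 (arginase 1), Clec4d (a myeloid lectin receptor) and Chil3 (a chitinase-like protein of macrophages) were detected on none of the uninjured arrays and were at least 43.2-fold, 49.4-fold and 37.5-fold higher after IR. Across these 10 genes the largest adjusted p was 7.64e-07. By the mean of all kept probes, Gpnmb rose by 3.49 in place of 6.98 and Tnc by 3.34.

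None of the 10 top decreases was in a fixed list. After Ces1d (log2 fold change -6.29 ± 0.12), Lrtm1 fell by 4.98 ± 0.11, and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, by 4.98 ± 0.13. Dhrs7c, a dehydrogenase of the same compartment, fell by 4.71 ± 0.11 and Art1, an ADP-ribosyltransferase, by 4.39 ± 0.09. Rpl3l, the striated muscle paralog of the ribosomal protein gene Rpl3, fell by 4.37 ± 0.06. The others were Yipf7 (-4.34), Inmt (-4.31), Doc2g (-4.24) and Hopx (-4.22), a homeodomain-only protein. The largest adjusted p among the 10 was 6.62e-06.

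Igf1 was higher on all 3 IR arrays than on any uninjured array, with a log2 fold change of 2.18 ± 0.10 (adjusted p = 1.27e-06), and a second Igf1 probe gave 2.74. Other members of the IGF axis list went both ways: of 16 measured, 5 rose and 9 fell, and the list as a whole did not pass (mean -0.31, adjusted p = 0.303), its mean turning to 0.19 with 7 rises and 3 falls under scaling to the median of all probes. Igfals, the subunit that stabilises circulating IGF complexes, fell by 2.70 ± 0.09 and was detected on 1 of 3 IR arrays, and Insr, the insulin receptor, fell by 2.04 ± 0.07. Igf1r, the IGF-1 receptor, had a log2 fold change of -0.71 ± 0.14 on its brightest probe (adjusted p = 0.00258), but 0.45 and 0.24 on the others kept. Each of those others lay near background and was detected on 4 of 6 arrays, against 6 for the brightest. The Igf1r value was -0.01 by the mean of probes, which includes these dim ones (adjusted p = 0.963). It was -0.06 under scaling to the median of all probes (adjusted p = 0.764), within a range of 0.000226 to 0.963 over all alternatives.

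Transcripts of the mouse mast cell chymase genes lay near background in both groups, which gives no measure of chymase protein. Mcpt4 had a log2 fold change of -0.17 ± 0.21 (adjusted p = 0.494), with 2 of 3 arrays of each group detecting it, and Cma1 of 0.14 ± 0.07 (adjusted p = 0.138), detected on 1 uninjured and 3 IR arrays and at 0.082 without uninjured array 110. Without uninjured array 109 the Mcpt4 value turned to 0.0060 (adjusted p = 0.980). Under scaling to the median of the kept probes Mcpt4 gave -0.69 (adjusted p = 0.00462) and Cma1 turned to -0.43 (adjusted p = 0.00922), within ranges of 0.00462 to 0.980 and 0.00922 to 0.436 over the alternatives. Of 7 measured mast cell list genes, Hdc (1.09 ± 0.25), the histamine-forming enzyme, Kit (0.80 ± 0.09) and Cpa3 (0.55 ± 0.13) rose and Gata2 (-1.47 ± 0.07) fell. The list did not pass (adjusted p = 0.710), and its mean of 0.14 turned to -0.14 under the kept-probe scaling. Under scaling to the median of all probes the mean was 0.52, with Hdc at 1.71, Kit at 1.42 and Gata2 at -0.84. Hdc, Kit and Gata2 are also expressed by other cell types.

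Among 21 measured cell death genes, 12 rose and 3 fell. Casp1, the inflammatory caspase, rose by 2.18 ± 0.12, Bid, a BH3-only protein undetected in uninjured hearts, was at least 3.56-fold higher, and Mlkl, the executor of necroptosis, rose by 2.17 ± 0.17 (1.38 by the mean of its probes). The list passed with a mean of 0.75 (adjusted p = 0.0471) but not with an estimated correlation (adjusted p = 0.190 with an estimated correlation), nor without IR array 106 (adjusted p = 0.0534). Its mean was 0.41 without background correction and 1.29 under scaling to the median of all probes. Casp1 and Mlkl are also expressed in macrophages, whose marker list rose in the same hearts. Adjusted p-values of the cell death list ranged from 0.00525 to 0.190 over the alternatives.

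**Figure D2:**
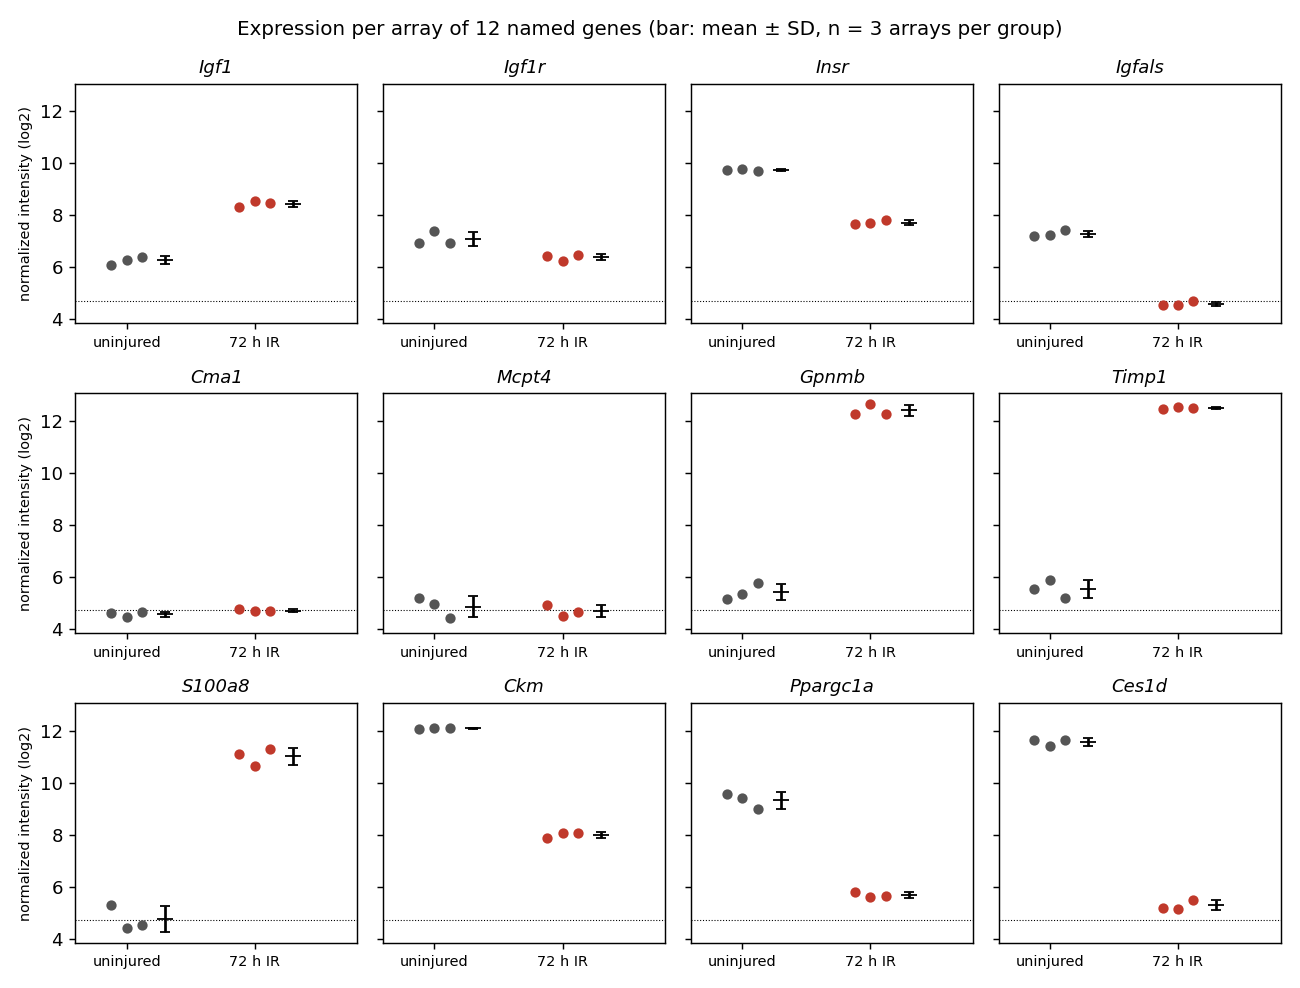
Normalized log2 intensity (vertical axis) of 12 genes on each of 3 uninjured (grey) and 3 IR arrays (red), with mean and SD beside the points and the mean lowest level of detected probes as a dotted line. Igf1 sits at 6.27 in uninjured and 8.44 in IR hearts, while Cma1 and Mcpt4 lie at the dotted line in both groups; Cma1 turned lower after IR under scaling to the median of the kept probes.

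Monocyte and macrophage transcripts rose in 21 of 22 measured genes, with a median log2 fold change of 2.91. Gpnmb, Lgals3 and Arg1 led the list, and Cd163 (-0.13) did not pass. The list test gave an adjusted p of 7.12e-09 (adjusted p = 0.0705 with an estimated correlation). All 11 measured neutrophil genes rose, led by S100a8, Clec4d and S100a9 (5.15 ± 0.31, detected on 1 of 3 uninjured arrays), with a mean of 3.06 (adjusted p = 5.25e-05) that was 1.71 without background correction and 1.98 with no filter, where 12 of 17 rose. Of the 11, 6 were undetected on all uninjured arrays and so passed the filter through the IR arrays alone. Among them Mpo and Retnlg were only at least 1.05-fold and 1.14-fold higher. Ngp, Camp, Mmp8, Ltf, Trem1 and Elane had no kept probe. The neutrophil list call was lost as well (adjusted p = 0.190 with an estimated correlation). Of 27 cytokine and chemokine genes, 24 rose and 2 fell. The monocyte attractants Ccl7 (5.26 ± 0.11) and Ccl8 (4.99 ± 0.13, detected on 1 of 3 uninjured arrays) and Ccl4 (5.09 ± 0.21, detected on 2) led, and Cxcl9 (-0.77) and Cxcl12 (-0.21) fell. The list had a mean of 2.20, or 1.32 without background correction, and an adjusted p of 6.41e-07 (adjusted p = 0.0705 with an estimated correlation). Its median of 2.08 became 1.84 with undetected genes set at their bound.

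Few genes of the lymphocyte lists were measured. Of 3 measured T cell genes, Il7r was at least 5.82-fold higher and Cd8b1 had a log2 fold change of 0.22 ± 0.07 (adjusted p = 0.0258, range 6.81e-05 to 0.150 over the alternatives), a call lost when any array other than 110 was left out, with arrays 106 to 110 alone (0.18, adjusted p = 0.150) and under the kept-probe scaling (0.16, adjusted p = 0.0796). Its value was 0.82 under scaling to the median of all probes and 0.45 by the mean of its probes. Cd3d (0.20) did not pass. Of 3 B cell genes, Blnk was at least 2.36-fold and Cd22 at least 1.21-fold higher, Cd22 losing its call under the kept-probe scaling (0.18, adjusted p = 0.287, range 9.51e-05 to 0.287 over the alternatives). Klrd1 of the NK cell list was at least 2.26-fold higher and Prf1 (-0.31) did not pass. In the dendritic cell and MHC class II list 6 of 8 genes rose, among them H2-DMb1 (1.21 ± 0.13), H2-DMa (0.95 ± 0.15) and H2-Ab1 (0.81 ± 0.16). Under scaling to the median of all probes 8 of 8 rose, with H2-DMa at 1.60, H2-Ab1 at 1.31 and a list mean of 1.09 in place of 0.63. As lists, T cell (adjusted p = 0.234), B cell (adjusted p = 0.217) and dendritic cell and MHC class II genes (adjusted p = 0.0843) did not pass. Interferon response genes rose in 16 of 17 cases, led by Isg15 (2.35 ± 0.26), Ifit3 (2.02 ± 0.23) and Oasl2 (1.94 ± 0.24, or 1.10 by the mean of its probes), with a list adjusted p of 0.00286 (adjusted p = 0.473 with an estimated correlation).

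All 30 measured extracellular matrix genes rose, with a median log2 fold change of 2.34. Timp1 (6.94 ± 0.16), Lox and Fn1 (4.23 ± 0.11), which encodes fibronectin, led, and the fibrillar collagens Col1a1, Col1a2 and Col3a1 rose by 3.86, 3.87 and 3.68. The list adjusted p was 4.80e-09 (adjusted p = 0.260 with an estimated correlation). All 10 measured genes of activated fibroblasts rose too, led by Lox, Tnc and Cthrc1, the last at least 20.1-fold higher. Postn (0.32, adjusted p = 0.0255) was undetected in uninjured hearts and showed no rise against its bound (0.96-fold). Their mean of 2.92 (adjusted p = 0.00015) was 1.91 without background correction, and the call was lost otherwise (adjusted p = 0.134 with an estimated correlation). Resident fibroblast genes were divided, 5 of 11 rising and 4 falling. Mfap5 rose by 2.54 ± 0.11, whereas Pi16 fell by 2.12 ± 0.13 and Gsn, the actin-severing gelsolin, by 3.22 ± 0.06 on its brightest probe and 0.69 by the mean of its probes. That list did not pass (adjusted p = 0.932), with a mean of -0.11 opposite in sign to its median of 0.17 and a mean of 0.38 under scaling to the median of all probes.

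Every one of the 23 measured cell cycle genes rose, at a median of 2.76. Prc1 (3.75 ± 0.19), a midzone protein of the dividing cell, Cdk1 (3.46 ± 0.10), the mitotic kinase, and Birc5 (3.42 ± 0.11) led. The list adjusted p was 1.46e-08 (adjusted p = 0.190 with an estimated correlation), and its mean of 2.56 was 1.49 without background correction. Lysosome genes rose in 14 of 14 cases, with the proteases Ctss (3.79 ± 0.18) and Ctsz (3.00 ± 0.09) and the glucuronidase Gusb (2.85 ± 0.13) at the top (adjusted p = 4.60e-06, and adjusted p = 0.0705 with an estimated correlation). Ribosomal protein genes rose in 13 of 13 cases, among them Rpl3 (1.77 ± 0.07), Rplp0 (1.56 ± 0.08) and Rps6 (1.49 ± 0.07). Their mean was 1.01 (adjusted p = 5.71e-05, and adjusted p = 0.172 with an estimated correlation), but 0.58 with 9 rising and 1 falling under the kept-probe scaling. Of 14 endoplasmic reticulum stress genes, 10 rose and 3 fell. The folding factors Sdf2l1 (2.86 ± 0.13), Creld2 (2.17 ± 0.11) and Pdia4 (2.04 ± 0.11) rose, and Herpud1 (-1.36), Ddit3 (-0.76) and Dnajb9 (-0.34), also induced by the unfolded protein response, fell. That list passed narrowly (adjusted p = 0.0418, and adjusted p = 0.446 with an estimated correlation) and not under scaling to the median of all probes (mean 1.42, adjusted p = 0.0963, range 0.00248 to 0.446 over the alternatives). Macrophage markers rose beside all of these groups.

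Genes of the cardiomyocyte contractile list fell in 17 of 18 measured cases, with a median log2 fold change of -1.57, while markers of macrophages rose. The list also holds genes outside the contractile apparatus, such as the creatine kinases Ckm and Ckmt2 and myoglobin (Mb). The decreases were uneven: log2 fold changes were -4.10 ± 0.08 for Ckm, muscle creatine kinase, -3.22 ± 0.07 for Tcap (telethonin) and -2.79 ± 0.07 for Myh6, the adult myosin heavy chain, but -0.39 for Myl2 and -0.22 for Hspb7, and Actc1 (0.04) did not pass. Myl2 and Actc1 had bright uninjured means (14.2 and 13.7), where changes can be compressed, but so had Tcap (13.7) and Myh6 (13.8). Hspb7 was dimmer (11.8). The list adjusted p was 4.63e-07 (adjusted p = 0.134 with an estimated correlation). Ion channel and calcium handling genes fell in 17 of 17 cases at a mean of -1.97, or -1.20 without background correction (adjusted p = 1.77e-07, and adjusted p = 0.0705 with an estimated correlation). Scn4b, a sodium channel subunit detected on 1 of 3 IR arrays, fell by 4.07 ± 0.10 and Kcnd2, a potassium channel, by 3.64 ± 0.12. Kcnv2 was at least 6.06-fold lower, and Ryr2, the calcium release channel, fell by 2.16.

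All 24 measured fatty acid oxidation genes fell, at a median of -2.31, led by the coactivator Ppargc1a (-3.64 ± 0.15), the isomerase Eci1 (-3.08 ± 0.07) and the kinase Pdk4 (-3.01 ± 0.10), with an adjusted p of 1.26e-10 (adjusted p = 0.118 with an estimated correlation). All 37 oxidative phosphorylation genes fell, at a median of -1.54, led by Cox7a1 (-2.35 ± 0.07), Cox8b (-2.24 ± 0.06) and Uqcrc1 (-2.08 ± 0.07), with an adjusted p of 8.62e-14 (adjusted p = 0.0705 with an estimated correlation). In the same hearts the contractile list had a median of -1.57 and the macrophage list of 2.91. Glycolysis and hypoxia response genes went both ways, 6 of 17 rising and 6 falling. Hmox1, heme oxygenase 1, rose by 5.06 ± 0.22 (detected on 1 of 3 uninjured arrays) and Pgam1 by 1.51 ± 0.09, and Vegfa fell by 2.29 ± 0.08. That list did not pass (adjusted p = 0.562), with a mean of 0.11, a median of -0.09 and a list test pointing down. Its mean turned to -0.10 under the kept-probe scaling. Under scaling to the median of all probes it was 0.56, with 8 rising and 5 falling.

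Genes of fetal type and wall stress rose in 7 of 11 cases and fell in 1. The natriuretic peptide gene Nppa rose by 1.83 ± 0.20 (1.20 under the kept-probe scaling) and Fhl1 by 1.70 ± 0.08, but Myh7, the fetal myosin heavy chain of the mouse, fell by 1.88 ± 0.12. The list mean was 0.76, or 0.40 under the kept-probe scaling, and the list narrowly missed the threshold (adjusted p = 0.0526) and passed under 7 alternatives, with adjusted p from 0.00525 to 0.330 over all of them. Of 16 endothelial genes, 8 fell and 2 rose, against 1 and 8 under scaling to the median of all probes, where the mean of -0.22 turned to 0.30, and the list did not pass (adjusted p = 0.216). Flt1 fell by 0.89 ± 0.07, Tie1 had a log2 fold change of -0.81 ± 0.08 and Sox17 of -0.57 ± 0.10. Under that scaling Flt1 gave -0.49, Tie1 lost its call (-0.17, adjusted p = 0.231, range 2.36e-05 to 0.231) and Sox17 turned to 0.086 (adjusted p = 0.509, range 0.000189 to 0.509), while the mean of probes gave -0.37 for Sox17. Smooth muscle and pericyte genes fell in 5 and rose in 3 of 10 cases (adjusted p = 0.269), led by Abcc9 (-2.68 ± 0.08), Rgs5 (-2.18 ± 0.11) and Smtn (-1.46 ± 0.09). Their mean of -0.68 was -0.11, with 5 rising and 5 falling and Smtn at -0.95, under scaling to the median of all probes.

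Red cell transcripts fell in 4 of 5 cases at a mean of -0.86. Alas2, the erythroid aminolevulinate synthase, fell by 1.65 ± 0.07 and Hba-a1 by 0.93 ± 0.06. Hbb-b2 was at least 1.69-fold lower, a call lost with arrays 106 to 110 alone (adjusted p = 0.0872, range 0.000264 to 0.0872). The list adjusted p was 0.0461 (adjusted p = 0.190 with an estimated correlation), and 0.0534 without IR array 106, within a range of 0.00378 to 0.190. Its mean was -1.31 under the kept-probe scaling, with Hba-a1 at -1.54, and Alas2 was at -1.03 under scaling to the median of all probes. Among 3 measured atrial myocyte genes, Dkk3 rose by 2.10 ± 0.08 and Kcnj3, detected on 1 of 3 IR arrays, fell by 1.31 ± 0.18. Their mean of 0.30 was 0.80 under scaling to the median of all probes and 0.14 under the kept-probe scaling. Atrial myocyte genes did not pass as a list (adjusted p = 0.748). Neither did mesothelial genes (adjusted p = 0.310), of which Krt8 was at least 2.34-fold higher and Upk1b rose by 1.23 ± 0.21, detected on 2 of 3 uninjured arrays. Cidea of the adipocyte list fell by 1.26 ± 0.08. From the skeletal muscle list Tnnt3 was at least 2.09-fold higher and Tnni2 rose by 0.81 ± 0.11. Scaling to the median of all probes gave -0.72 for Cidea and 1.44 for Tnni2.

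Of the 28 lists tested, 11 passed upward and 5 downward, and none of these 16 calls held with an estimated correlation. In each of the 28 lists the numbers of genes that rose and fell, adjusted over the list alone, equalled those over all genes tested.

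**Figure D3:**
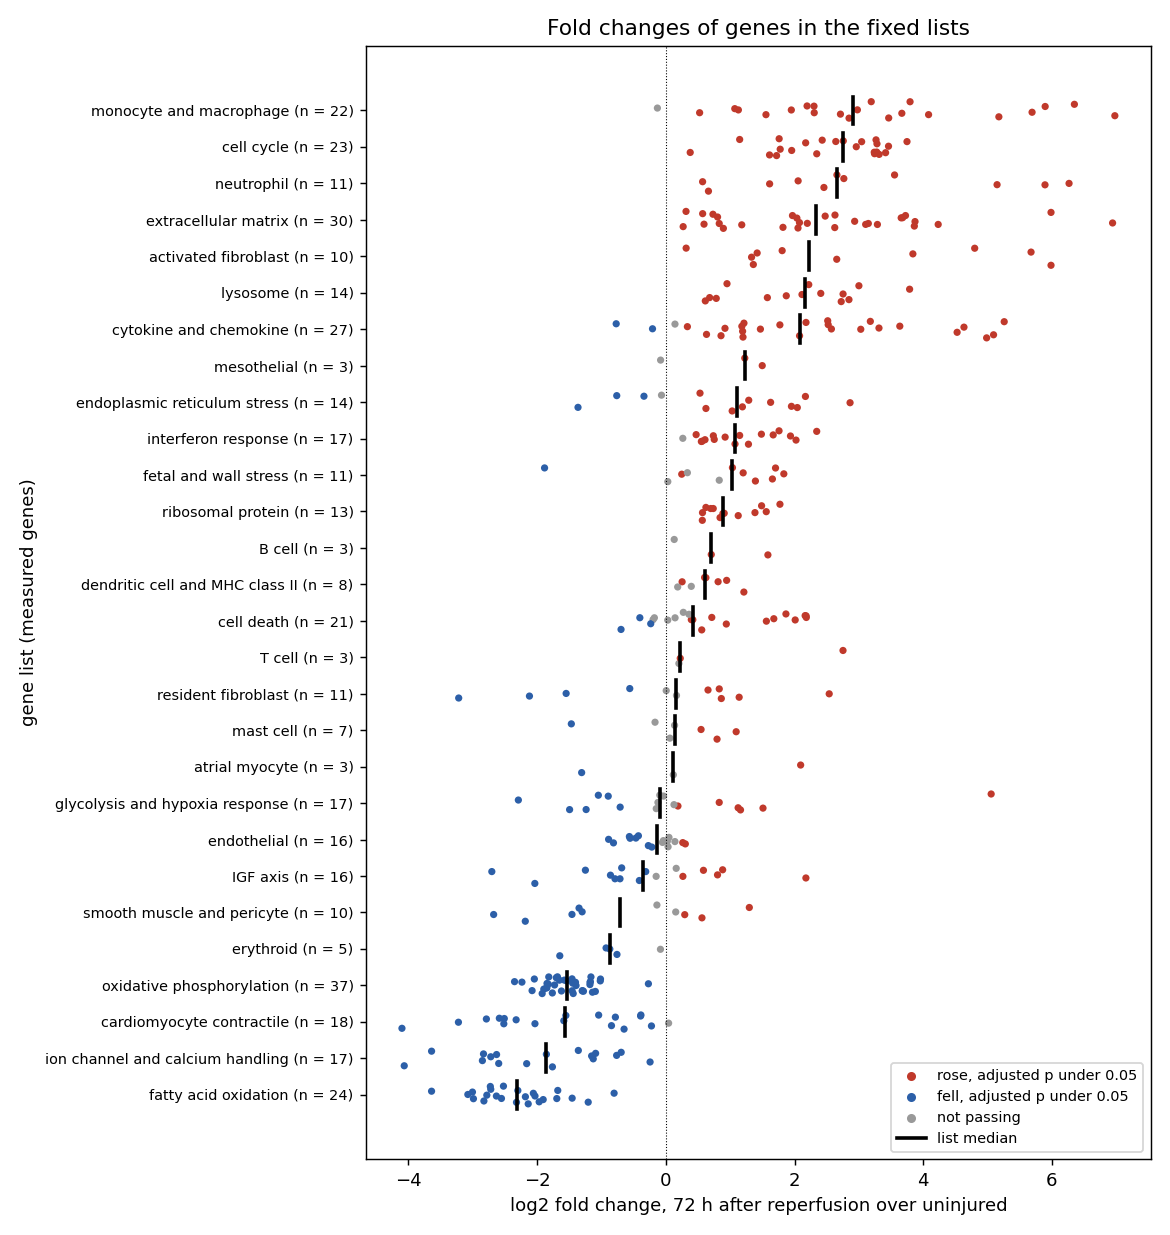
Log2 fold change (72 h after IR over uninjured, horizontal axis) of each measured gene of the 28 tested lists (vertical axis, with the number of genes), red where it rose, blue where it fell, grey where it did not pass, and a black line at the list median. Medians run from -2.31 for fatty acid oxidation to 2.91 for monocytes and macrophages; the endothelial and IGF axis lists have negative medians here, and their means turned positive under scaling to the median of all probes.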

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

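The alternatives added after the data were seen were scaling to the median of the kept probes, a block for the number series of the arrays (106 to 110 against 886 and 904), the 4 arrays 106 to 110 alone, and the authors' processed values with a replicate block. Over the 18 alternatives that give a count, 6928 to 7873 genes changed, against 7545, with 7037 to 7560 when each array was left out and 7489 with the number series as a block. Genes changed by at least 2-fold numbered 1542 to 3695, the highest under scaling to the median of all probes, with 1542 without background correction and 1671 with the authors' values, both of which keep the background in the signal and so compress folds of dim genes. With each list's correlation estimated, all 16 list calls were lost at unchanged means: cardiomyocyte contractile -1.64, monocyte and macrophage 3.17, neutrophil 3.06, activated fibroblast 2.92, erythroid -0.86, cell death 0.75, extracellular matrix 2.48, cell cycle 2.56, fatty acid oxidation -2.30, oxidative phosphorylation -1.53, cytokine and chemokine 2.20, interferon response 1.15, ion channel and calcium handling -1.97, lysosome 2.02, endoplasmic reticulum stress 0.91 and ribosomal protein 1.01. The test with an estimated correlation has only the degrees of freedom of 6 arrays. Estimates lay below the preset 0.01 for ion channel (-0.00014), lysosome (-0.034), erythroid (-0.11) and cell death genes (0.0059). The calls of these lists were lost all the same, so correlation between their genes does not account for the loss. The fetal and wall stress list (mean 0.76) passed without background correction (0.79), with the authors' values (0.79), at offset 50 (0.79), with no filter (0.76) and with a trended robust variance (0.76), and its means without each array were 0.69 to 0.83, passing without uninjured array 110. The dendritic cell and MHC class II list passed with no filter (0.39), and the endoplasmic reticulum stress list did not under scaling to the median of all probes (1.42). Erythroid means without each array were -0.88 to -0.81 and cell death means 0.72 to 0.79, both losing their call without IR array 106. Sox17 turned to 0.086 under scaling to the median of all probes and Cma1 to -0.43 under the kept-probe scaling, and Mcpt4 to 0.0060 without uninjured array 109 (range without each array -0.39 to 0.0060). The list test, not passing in any of these settings, turned direction for mast cell genes (0.52 under scaling to the median of all probes, -0.14 under the kept-probe scaling) and resident fibroblast genes (0.38 under the former, and without array 109, with means of -0.14 to -0.095 without each array). For these list and gene changes the cause was not tested. Of 1760 values of named genes under alternatives, 1744 kept direction and side of the threshold, 12 lost a call, 1 gained 1 and 3 turned. With the replicate block on the authors' values 7438 genes changed against 7534 without it, 1671 by at least 2-fold, and the fetal list had a mean of 0.79 and passed. Arrays with the same replicate number did not deviate together (correlations of -0.036, -0.011 and -0.071 across genes, against -0.015 to 0.054 for different numbers). With 3 arrays per group this shows no sign of a pairing but cannot exclude one. The signal table carries no replicate number, so the block was run only on the authors' values. Genes near background, such as Cma1 and Mcpt4, are limited by signal over background, and 521 genes had no detected uninjured signal.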

Other observations

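Groups of genes sharing the first 3 letters of their symbol, 106 groups of at least 15 genes, were tested with camera after the results were seen. Of these 15 passed, and none did with an estimated correlation. Genes starting with Mrp, mostly mitochondrial ribosomal proteins, fell in 62 of 72 cases and rose in 3 (mean log2 fold change -0.70, adjusted p = 3.68e-09, and adjusted p = 0.220 with an estimated correlation), or 35 and 11 with a mean of -0.22 under scaling to the median of all probes. Mrps35 (-2.06 ± 0.07) and Mrpl42 (-1.92 ± 0.06) led. None of these genes was in a fixed list. In the same hearts the contractile list had a median of -1.57 and the macrophage list of 2.91, and a change of cell make-up was not tested for the Mrp genes. Cytosolic ribosomal protein genes starting with Rpl went the other way, 30 of 34 rising and 2 falling (adjusted p = 6.88e-05, and adjusted p = 0.339 with an estimated correlation), or 21 and 5 under the kept-probe scaling. The paralogs Rpl3 and Rpl3l moved in opposite directions, at 1.77 ± 0.07 and -4.37 ± 0.06 (SE, n = 3 per group).

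Glutathione transferase genes, starting with Gst, fell in 15 of 20 cases with none rising (mean -1.03, adjusted p = 0.00147, and adjusted p = 0.446 with an estimated correlation), or 12 falling and 4 rising with a mean of -0.52 under scaling to the median of all probes. Gstm7 (-3.17 ± 0.11) and Gstk1 (-2.60 ± 0.07) led. Genes starting with H2a, mainly histones H2A, rose in 14 of 17 cases and fell in 3 (adjusted p = 0.00421, and adjusted p = 0.517 with an estimated correlation), led by H2ac12 (3.97 ± 0.12) and H2ac15 (3.88 ± 0.20), whose probes can bind near-identical copies. Sorting nexins, starting with Snx, rose in 20 of 28 cases and fell in 2 (adjusted p = 0.00496, and adjusted p = 0.310 with an estimated correlation). In the same hearts the contractile, macrophage and cell cycle lists had medians of -1.57, 2.91 and 2.76. A change of cell make-up was not tested for the Gst, H2a or Snx genes. Among 2481 kept probes with no gene name here, 864 rose and 783 fell. The median SD per gene was 0.12 among uninjured and 0.08 among IR arrays.

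Of the tests that follow, the limit on bright probes, the comparison within classes of brightness and the move of the share under other scalings were chosen only after the results were seen. Of the 10 splits of the 6 arrays into 3 and 3, the real split called 7545 genes, the highest of the others called 0, and 1 split of 10 reached the real count, which is too few splits for a share under 0.05. The measured mast cell proteases Cma1, Mcpt4 and Cpa3 spanned 0.715 on the log2 scale, all near background, so a change in the number of mast cells was left undecided.

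A lower share of cardiomyocyte RNA may account for the fall of the fatty acid oxidation list, but it predicts a similar fall of the contractile list, and the medians differed by -0.74 (24 against 18 genes, two-sided permutation p = 0.0230), past the bound of 0.3 set before the data were examined. That bound did not allow for brightness, and 9 of 18 contractile but 5 of 24 fatty acid oxidation genes had an uninjured mean of at least 13 on the log2 scale, where changes can be compressed, although Tcap (-3.22) and Myh6 (-2.79) fell strongly from such levels. Among genes below 13 the difference was -0.52 (19 against 9 genes, exact permutation p = 0.114), and at 13 or above the medians were -1.69 and -0.78. Weighted over both classes the difference was -0.65 (exact permutation within classes, two-sided p = 0.0879), further than 0.3 from 0 but not past the test. The contractile list also holds creatine kinase and myoglobin genes, which these tests did not set apart. With so few genes per class, a lower share, a difference in brightness and lower expression within cardiomyocytes cannot be told apart for the fatty acid oxidation list.

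Macrophage markers rose in hearts where contractile genes fell, and a smaller share of cardiomyocyte RNA would raise the markers of every other cell type alike. The median of the monocyte and macrophage list lay 3.05 above that of the endothelial list (22 against 16 genes, two-sided permutation p = 0.00072). That p treats genes as independent and does not measure the spread between arrays. With each array left out in turn, the list means stayed at 3.15 to 3.20 and at -0.23 to -0.19. This gap argues against that account as the whole cause. More macrophages in the tissue, and more of these transcripts per cell, both stay open and were not tested against each other.

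More changed genes rose than fell, and quantile normalization, which forces equal intensity distributions, is a candidate explanation for the size of that share. The share moved by up to 24.1 percentage points from 53.3%, under scaling to the median of all probes, which is the level of an undetected probe. Under the kept-probe scaling it was 42.7%, so the direction of the balance is set by the scaling. A true rise in the total number of expressed transcripts after IR stays open. The raw median, also the level of an undetected probe, was higher on the IR arrays (89.9 to 91.9 against 83.2 to 86.1). The raw maximum was lower (16845 to 17260 against 20059 to 22057), and no sample amounts or spike-ins were used here.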
